A study of Ambystoma mexicanum with 1604 samples.

How the data were processed

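The series holds single-cell transcriptomes of axolotl forelimb tissue in 1604 deposited samples, which fall into 18 groups by line, method, tissue and day. In 10x Genomics samples (Chromium 3' kits) a sample is a library of many cells. In the plate-based samples (Fluidigm C1 or SmartSeq2) a sample is a single cell. dpa stands for days after amputation, 3mpa and 1apa are the names the labels give to the latest limbs, and CT stands for connective tissue. The CT-enriched 10x libraries come from Prrx1:Cre-ER animals sorted by FACS and cover uninjured upper arm and blastema at 18, 25 and 38 dpa, with 2 libraries per group. A further pair of uninjured libraries was not enriched. The plate-based groups cover sorted Prrx1:Cre-ER cells (uninjured, 3, 5, 8, 11 and 18 dpa, 3mpa and 1apa), unsorted limb fields or buds at stages 28, 40 and 44, and sorted Col1a2:ER-Cre-ER cells at 11 dpa. Prrx1 cells and stages 40 and 44 were measured with C1, and stage 28 and the Col1a2 cells with SmartSeq2.

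For the 10x libraries the authors deposited raw UMI counts per transcript contig and barcode, and tables of raw UMI counts per gene symbol for the cells they kept. The deposited gene tables of CT-enriched uninjured and blastema cells lack every symbol that starts with RP, and the rule by which the authors kept cells is not given in the sources used here. For the plate-based cells the authors deposited values that behave as log2(TPM + 1), a scale read from the values themselves because the labels do not state it. Cell Ranger 2.0.0, kallisto and STAR are named in the submitters' processing notes. The genome or transcriptome build, the aligner role of each tool and the annotation are not given in the sources used here. Other columns of the deposited tables hold the authors' cell class, cluster, plate or time point, and the barcode and contig lists give the order of the matrices.

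Cells in the tables were matched to barcodes by their number, and no doublet caller was run, so the authors' cell sets were kept as they were. The 6 blastema 10x libraries carry an uninjured tissue label beside a blastema source name, and the source name was followed. A plate-based set labelled 3mpa appears as 1apa in the deposited table, and the sample label was followed. Of the Col1a2 line, the 36 uninjured cells have no values in the tables used, so the planned contrast of that line against its own uninjured cells was not made.

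UMI counts of all cells kept by the authors were summed per library, symbols that occurred more than once were added together, and the 8 CT-enriched libraries entered a single edgeR fit without covariates. The tests used edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, with TMM factors, the default filterByExpr filter, glmQLFit, glmQLFTest and Benjamini-Hochberg adjustment at a threshold of 0.05 within each contrast. Enrichment was tested in a separate fit of the 4 uninjured libraries on contigs, summed over every deposited barcode whether or not the authors kept it, because composition differs strongly there. In that comparison, 8215 symbols were paired with exactly 1 of 91648 contigs from cells present in both kinds of deposit (at least 10 UMIs), and 2 symbols with contradicting pairs were dropped. Levels are given as CPM (UMI counts scaled to the library) after TMM scaling unless they are said to be per plain library total. Where every library of a group had a count of 0, the fold is given as a lower bound from a floor of 3 counts over the group. Fold intervals and floors cover counting error only.

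Gene lists were tested with camera at its preset correlation of 0.01 and again with an estimated correlation, with fry beside them, and p-values were adjusted by Benjamini-Hochberg over the lists of a contrast. Camera compares a list with the other genes, whereas fry asks only whether the list's own genes changed. A list needed 3 measured members. The 17 tested lists were fibroblastic CT, tenocyte, periskeletal, chondrocyte, osteoblast or hypertrophic, limb progenitor and patterning, S phase, G2 and M phase, wound inflammation, matrix degradation, mature extracellular matrix, provisional extracellular matrix, contractile and cytoskeletal, ribosome biogenesis, glycolysis and hypoxia, immediate early and dissociation stress, and Wnt Bmp and Tgf-beta signalling. The fibroblastic CT and mature extracellular matrix lists both hold LUM, DCN, COL3A1, FBN1, OGN and FBLN1, so their results are not independent. Another 12 lists hold markers of epidermis, connective tissue, skeletal muscle, endothelium, pericyte or smooth muscle, macrophage, neutrophil, lymphocyte, erythroid, Schwann, thrombocyte and melanocyte cells.

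The authors' clusters were used for the cell classes of the libraries that were not enriched, with Leiden clusters at resolution 0.5 and 2 (scanpy 1.11.5, counts scaled per cell) and the highest marker score per cell as alternatives. A cluster took the name of the marker list with the highest mean score among lists with at least 3 markers detected in at least 5% of its cells and at least 1 marker among its 10 leading genes, and otherwise stayed unnamed. A cell was scored as cycling when its S phase and G2 and M phase genes held more than 54.6 UMIs per 10000, the 95th percentile of the uninjured cells. Class shares carry exact Clopper-Pearson intervals (95%).

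In the plate-based groups no animal is named, so no test was run. A set is the group of cells that share a title prefix. Group levels are equally weighted means of set means of log2(value + 1), and a gene passes the size rule when its difference from uninjured is at least 2 and every set lies beyond every uninjured set. A list median is placed among 10000 random lists matched on mean expression and reported as a percentile. Similarity is the Pearson correlation between group profiles over the 1000 genes most variable between groups. Similarity between cells is the median Spearman correlation over pairs of cells of a set, also within a window of 2000 to 3000 detected genes (at least 10 cells). Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for these steps.

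Genes are named by a fixed rule. The Cre driver genes PRRX1 and COL1A2 are named throughout. For a 10x contrast the rule takes the 10 highest and 10 lowest log2 fold changes among genes with adjusted p under 0.05, mean log2 CPM of at least 5, a symbol and separated libraries, and up to 4 changed members of each list. For a plate-based contrast it takes the 5 highest and 5 lowest differences that pass the size rule and up to 4 members of each list.

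The groups, contrasts, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The cycling threshold, the details of cluster naming, the window of detected genes, the use of the mean correlation with stages 40 and 44 and of the mature extracellular matrix median as summarising values, the comparison of barcodes outside the tables by a 10-fold rule and 3 further alternatives were set after values had been seen. The alternatives comprised median-of-ratios and upper-quartile scaling, DESeq2 1.42.0, no filter beyond 1 count, fits of the 2 groups alone, leaving out each library or set, thinning to 1974400 UMIs, removal of cells scored as cycling, a log2 fold threshold of 1 (glmTreat), other pseudocounts (0.1 and 10), a filter on mean value (5), equal weight per cell, the share of cells above 1, quantile normalization, and other gene sets and correlations for similarity. Those chosen later were the uninjured connective tissue cells that the authors kept from the libraries that were not enriched, and values rescaled to an equal total per cell for list medians and for similarity. The planned number of genes that pass the size rule in plate-based groups is not given, because a group there is 1 sample per cell without named animals.

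Simulated data were passed through the same code. Among 8534 genes of simulated counts set like the comparison of 18 dpa with uninjured, 99% of the 4-fold and 86% of the 2-fold changes were called (100 genes each), and 10 of the called genes (5.13%) were false. In simulated counts set like the enrichment comparison (13932 genes) the shares were 99% and 77%, with 6 false calls (3.30%). None of 20 unchanged lists was called and the changed list was. These simulated genes varied independently and with a fixed dispersion. The simulations therefore do not show how often lists of correlated genes are called falsely, such as G2 and M phase with an estimated correlation of 0.76 at 18 dpa. Nor do they cover genes whose spread between libraries differs from that dispersion. For the plate-based code, 167 of 200 genes changed 16-fold (83.5%) passed the size rule with 100 cells and 15286 genes, no unchanged gene passed, and 2 of 50 unchanged lists fell outside the central range. The simulated cells were drawn from the pooled uninjured sets, so an unchanged gene could hardly pass. Differences between sets and in genes detected were not simulated, so false passes in the real groups were not measured. The code for the 10x tests and for the plate-based contrasts was first run on the real data, then on these simulated data, and the results did not change.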

Results

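Connective tissue cells of the 18 dpa blastema held far fewer transcripts of several fibrous matrix genes than CT-enriched cells of the uninjured arm and more of cartilage matrix and cell division genes. The gap was deep at 18 and 25 dpa and smaller at 38 dpa, while the cartilage genes stayed high. Its size, and at 38 dpa its direction for several genes, depended on which uninjured cells were the reference. In plate-based cells lower matrix genes were already present at 3 dpa, together with high proteinase and provisional matrix genes. At 18 dpa the matrix degradation genes were near the uninjured level and the cartilage genes were highest.

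At 18 dpa against uninjured arm, several structural genes of fibrous tissue were among those that fell furthest. TNXB, a tenascin of mature connective tissue, fell by 8.76 on the log2 scale (SE 0.17, adjusted p = 4.6e-16, edgeR quasi-likelihood test, Benjamini-Hochberg), from 774 and 860 CPM in the uninjured libraries to 1.92 and 1.83. The elastic fibre genes FBN1 (log2 fold change -7.39, SE 0.17) and MFAP5 (-6.71, SE 0.17) and the dermal matrix gene DPT (-5.14, SE 0.15) fell as well, and DPT went from 8223 and 7889 CPM to 250 and 209. SI:DKEY-178E17.3 (-8.10), SI:CH1073-126C3.2 (-7.30), GIG2P (-6.68), FAM198B (-6.16), CYP2A13 (-5.80) and ITIH5 (-5.61) were also among the lowest. COL1A2, which encodes a chain of type I collagen and drives 1 of the Cre lines, fell by 2.48 (SE 0.14), from 38617 and 38796 CPM to 5969 and 7940. Of 10 measured fibroblastic CT genes 8 fell and 2 rose, the same 8 and 2 when adjusted over the list alone (median -2.85, camera adjusted p = 2.4e-18). Of 14 mature extracellular matrix genes 13 fell and 1 rose, also when adjusted over the list alone (median -2.50, camera adjusted p = 5.5e-20). COL6A1 (-4.41), PRELP (-4.25) and OGN (-3.43) were among those that fell. The mature extracellular matrix and fibroblastic CT lists share members, so here and in later comparisons they are not separate evidence.

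The size of these falls depended on the reference. Against the uninjured connective tissue cells that the authors kept from the libraries without enrichment, TNXB stood at -7.31, FBN1 at -5.03, MFAP5 at -4.07, DPT at -3.90 and OGN at -0.70, while COL1A2 stood at -0.30 and lost its call (adjusted p = 0.060, edgeR quasi-likelihood test, Benjamini-Hochberg). Of 74 named genes with a call at 18 dpa 63 kept it against that reference, 4 lost it (COL1A2, TNMD at -0.12, SDC1 at 0.20 and FBL at 0.19) and 7 reversed. The cells compared also sat in different clusters of the authors. At 18 dpa the clusters led by OTOS, LECT1 and COL2A1 and by MDK, COL2A1 and OTOS held 233 and 528 of 2684 cells in the first library and 371 and 2157 of 7255 in the second, while among uninjured cells, clustered in another table, the only cluster like chondrocytes by its markers (led by CTGF and COL11A1) held 10 of 350 and 14 of 674. A change within cells was therefore not told apart from a change in which cells were present.

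Cartilage and patterning genes rose at the same day. OTOS rose 212-fold (log2 fold change 7.73, SE 0.37, adjusted p = 2.0e-11, edgeR quasi-likelihood test, Benjamini-Hochberg) and EPYC, a cartilage proteoglycan, by 5.18 (SE 0.30), from 0.534 and 5.61 CPM to 141 and 134. SOX9, the transcription factor of cartilage precursors, rose by 4.94 (SE 0.25). COL9A1 was absent from both uninjured libraries and at least 3.37-fold higher at 18 dpa (1.92 and 1.79 CPM), and HAPLN1 stood at 12.4 and 9.84 CPM against 0 and 0.281. Of 11 measured chondrocyte genes 10 rose, also when adjusted over the list alone (camera adjusted p = 1.1e-07, but adjusted p = 0.08 with an estimated correlation). HOXA13, which marks the hand region, was at least 20.5-fold higher (11.7 and 11.0 CPM against 0 and 0), and SHH, the posterior signal of the limb bud, at least 3.86-fold higher (2.13 CPM in both libraries against 0). MSX1 (1.96, SE 0.42) and LHX2 (1.83, SE 0.24) rose too. Of 11 limb progenitor and patterning genes 7 rose and 4 did not pass, also when adjusted over the list alone, and the list as a whole had adjusted p = 0.073 (camera) and adjusted p = 0.0010 (fry). Among genes with mean log2 CPM of at least 5, PRDX2, a peroxide-reducing enzyme, rose most, 989-fold (9.95, SE 0.25), from 0.534 and 1.12 CPM to 998 and 832. It is also a leading gene of red blood cell-like cells in the arm. AW551984 (7.50), NRGNA (7.48) and S100A10B (6.90) rose strongly as well. Further genes with 3 or fewer counts in the uninjured arm were ECM2 (35.6 and 40.1 CPM at 18 dpa against 0 and 0.842) and FXYD3 (33.1 and 40.1 against 1.60 and 0). Against uninjured cells that were not enriched, PRDX2 stood at 6.21, S100A10B at 1.56, FXYD3 at 3.26 and LHX2 at 1.12. The other genes named in this paragraph stood no lower there than against CT-enriched cells, with OTOS at 12.98 and ECM2 at 12.32.

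Cell division genes rose in nearly every member. Of 11 S phase genes 9 rose, 10 when adjusted over the list alone, among them RRM1 (2.74), MCM7 (2.60), MCM4 (2.33) and CDC6 (2.25), with a camera adjusted p = 2.5e-07 and adjusted p = 0.091 with an estimated correlation. Of 14 G2 and M phase genes 13 rose, 14 when adjusted over the list alone, with the mitotic checkpoint gene MAD2L1 (5.11, outside the list), PLK1 (4.17), UBE2C (3.71), AURKB (3.53) and CDK1 (3.47) as examples (camera adjusted p = 1.0e-08, adjusted p = 0.28 with an estimated correlation). CDC6 stood at -0.34 without the cells scored as cycling. Those cells made up 63.5% and 65.7% of the 18 dpa libraries. The shares in the uninjured libraries (5.71% and 4.75%) follow from the threshold, which was a percentile of those same uninjured cells. They are therefore not a measured rate of division in the uninjured arm. Ribosome biogenesis genes rose in 6 of 9 and fell in 1, also when adjusted over the list alone, with HSPD1 (2.09), DKC1 (1.62), NCL (1.54) and FBL (1.53) leading (camera adjusted p = 0.0014, adjusted p = 0.091 with an estimated correlation).

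Other groups were mixed at 18 dpa. All 4 measured tenocyte genes fell, also when adjusted over the list alone, MKX by 2.37, TNMD by 1.05, THBS4 by 0.90 and KERA by 0.66. The list did not pass camera (adjusted p = 0.14) but passed fry (adjusted p = 0.00044). KERA stood at 0.16 against uninjured cells from the libraries that were not enriched. Of 5 contractile and cytoskeletal genes 4 fell (CNN2 -4.42, TPM2 -1.36, list adjusted p = 0.16, camera), and of 6 matrix degradation genes 4 fell, with PLAU at -2.45 and MMP14 at -1.06 (list adjusted p = 0.15, camera), the same numbers when adjusted over the list alone. PLAU and MMP14 stood at 0.14 and 0.76 against uninjured cells that were not enriched. The wound inflammation list held 2 falls (PTGS2 -3.23, TNFAIP6 -1.98) and 1 rise (SOD2 0.89) among 5 genes (camera adjusted p = 0.51). Provisional extracellular matrix genes went both ways, SDC1 up by 1.58 and VCAN by -0.88, and this list's median (-0.24) differed in sign from its mean (0.06) and its test (camera, up, adjusted p = 0.98). Of 7 glycolysis and hypoxia genes 3 rose and 3 fell (TPI1 0.82, ENO1 0.65, ALDOA -0.57, camera adjusted p = 0.58), and SLC2A1 stood at 16.4 and 20.4 CPM against 0.534 and 0.561. The immediate early and dissociation stress list had JUN up by 1.90 and DUSP1 (-1.99) and JUNB down among 7 genes (camera adjusted p = 0.51), with 2 rises and 3 falls when adjusted over the list alone. Among 10 genes of Wnt Bmp and Tgf-beta signalling 2 rose and 5 fell, with DKK1 at 3.89, ID1 at -2.37, TGFB1 at -2.31 and DKK3 at -2.22 (camera adjusted p = 0.25). The osteoblast or hypertrophic list had 1 rise, ALPL (0.86), and 1 fall, IBSP (-3.09), among 3 genes. IBSP came from a single uninjured library (214 against 0.534 CPM) and reversed to 4.68 without it. That list's median of -1.12 was opposite in sign to its test (camera, up, adjusted p = 0.98). VCAN and JUNB stood at 0.56 and 0.70 against uninjured cells that were not enriched, and ALDOA at 0.01 without cells scored as cycling. The 2 measured periskeletal genes did not pass and were too few for a test. By fry the Wnt Bmp and Tgf-beta signalling, matrix degradation and contractile lists passed (fry adjusted p = 0.0012, 0.0034 and 0.0052). So did the immediate early and wound inflammation lists (fry adjusted p = 0.016 and 0.023). The provisional extracellular matrix, glycolysis and hypoxia, and osteoblast or hypertrophic lists did not pass fry.

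In all, 4891 of 8899 genes changed at 18 dpa, 2627 up and 2264 down (edgeR quasi-likelihood test, Benjamini-Hochberg, 0.05), and 1874 passed when a log2 fold change of 1 was the null. Depth differed between the groups, from 1974400 to 33080431 UMIs per library, and p-values here measure only the spread between libraries, which can be technical because the labels do not say that libraries came from separate animals. Upper-quartile scaling moved the median of all genes by -0.126.

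**Figure D1:**
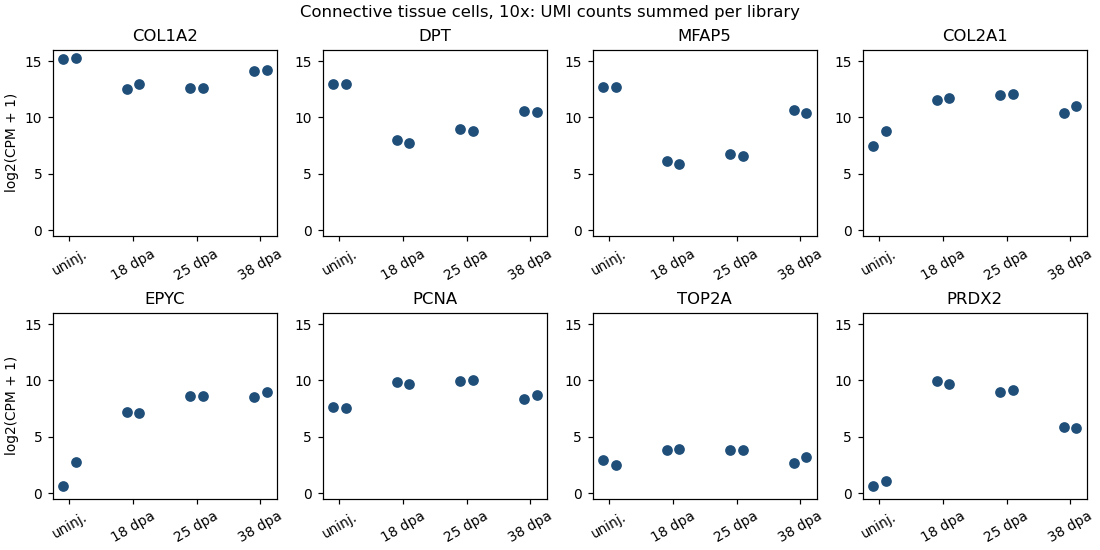
Expression of 8 genes in CT-enriched 10x libraries, as log2(CPM + 1) of summed UMI counts against group (uninjured, 18, 25 and 38 dpa), 2 libraries per group. DPT fell by 5.14 at 18 dpa and PRDX2 rose by 9.95 on the log2 scale.

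At 25 dpa the fibrous matrix genes were still far below the uninjured arm, and cartilage genes were far above it. TNXB (-6.07), MFAP5 (-6.05, SE 0.17), FBN1 (-5.56, SE 0.16), RARRES1 (-5.48), CLEC3B (-5.26), TIMP4 (-5.08), CLU (-5.08), DPT (-4.11) and OGN (-3.04) fell, and COL1A2 fell by 2.65 (SE 0.15, adjusted p = 1.3e-10, edgeR quasi-likelihood test, Benjamini-Hochberg). Fibroblastic CT genes fell in 8 of 10 and rose in 1, also when adjusted over the list alone (camera adjusted p = 6.1e-19), and mature extracellular matrix genes fell in 12 of 14 and rose in 1 (median -2.43, camera adjusted p = 6.1e-19). EPYC rose by 6.67 (SE 0.29) to 389 and 387 CPM and MATN1, another cartilage matrix gene, by 5.77 (SE 0.43) to 264 and 321 CPM from 5.87 and 5.05. OTOS (8.64), PRDX2 (9.15, or 5.39 against uninjured cells that were not enriched), AW551984 (6.99) and NRGNA (6.81) also rose, and COL9A1 was at least 3.96-fold higher. Chondrocyte genes rose in 10 of 11, also when adjusted over the list alone (camera adjusted p = 6.4e-12). HOXA13 was at least 47.7-fold higher (28.5 and 24.6 CPM against 0 and 0), and MSX1 (2.40) and LHX2 (1.93) rose. The limb progenitor and patterning list had 5 rises and 1 fall among 11 genes (camera adjusted p = 0.069).

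All 11 S phase genes rose at 25 dpa (CDC6 2.74, MCM7 2.69, RRM1 2.67), and PCNA, the sliding clamp of replication, rose by 2.41 (SE 0.13), from 194 and 186 CPM to 982 and 1033 (camera adjusted p = 3.9e-10, adjusted p = 0.078 with an estimated correlation). G2 and M phase genes rose in 12 of 14, with PLK1 at 4.20 and UBE2C at 3.90 (camera adjusted p = 1.7e-08, adjusted p = 0.23 with an estimated correlation). Ribosome biogenesis genes rose in 6 of 9 and fell in 1 (camera adjusted p = 0.026, adjusted p = 0.17 with an estimated correlation). Tenocyte genes fell in 3 of 4, and in 4 when adjusted over the list alone, TNMD by 1.79, KERA by 1.53 and THBS4 by 0.75 (camera adjusted p = 0.026, adjusted p = 0.17 with an estimated correlation), and contractile and cytoskeletal genes in 4 of 5, CNN2 by 3.45 and TPM1 by 1.34 (camera adjusted p = 0.026, adjusted p = 0.26 with an estimated correlation). WIF1, 1 of 2 measured periskeletal genes, fell by 3.03. THBS1 (1.40), SDC1 (1.48), TIMP1 (0.66) and ID3 (2.18) rose, and VCAN (-1.32), MMP1 (-1.77), PLAU (-1.95), DUSP1 (-2.02), JUNB (-1.95), TGFB1 (-2.15) and ID1 (-2.86) fell. Against uninjured cells that were not enriched, VCAN and PLAU stood at 0.12 and 0.63, COL1A2 at -0.48 and OGN at -0.33, and of 75 named genes with a call 61 kept it, 7 lost it (among them THBS1 at 0.15, SDC1 at 0.09, JUNB at -0.26, WIF1 at -1.54 and THBS4 at -0.16) and 7 reversed. SLC2A1 stood at 19.0 and 22.2 CPM and ENO1 rose by 0.79. In all 4554 genes changed, 2424 up and 2130 down.

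By 38 dpa much of the fibrous matrix had come back relative to 18 dpa, yet in the cells the authors kept it stayed below the CT-enriched uninjured cells. Barcodes left out at 38 dpa were richer in connective tissue markers than the kept cells, with values given in the closer look below. COL1A2 fell by only 1.06 against uninjured (SE 0.14, adjusted p = 1.2e-05, edgeR quasi-likelihood test, Benjamini-Hochberg), with 17928 and 19278 CPM. DPT (-2.46, SE 0.13), MFAP5 (-2.17), FBN1 (-1.95), OGN (-1.57), COL1A1 (-1.42) and COL6A1 (-2.45) fell. Fibroblastic CT genes fell in 9 of 10, also when adjusted over the list alone (median -1.07, camera adjusted p = 1.0e-11), and mature extracellular matrix genes fell in 10 of 14 and rose in 1 (median -0.97, camera adjusted p = 4.5e-06, adjusted p = 0.18 with an estimated correlation). These directions depend on which uninjured cells are the reference. Against the uninjured connective tissue cells that the authors kept from the libraries without enrichment, COL1A2 stood at 1.07, COL1A1 at 0.70, OGN at 1.10, FBN1 at 0.35 and MFAP5 at 0.41, and of 71 named genes with a call 53 kept it, 3 lost it (among them TGFB1 at -0.10) and 15 reversed. The cells compared also sat in different clusters of the authors. The blastema cluster led by COL1A1, COL1A2, FBN1 and MFAP5 held 351 of 576 and 1243 of 2285 cells at 38 dpa but 50 of 2684 and 89 of 7255 at 18 dpa, so a return within cells was not told apart from a change in which cells were present. The lowest genes beyond those named were SI:CH1073-126C3.2 (-4.75), RARRES1 (-3.58), MGC75752 (-3.34), CLEC3B (-3.29), CYP2A13 (-3.25), BHMT (-3.02), PTX3 (-2.92), APOH (-2.90), PPAP2B (-2.88) and HEBP2 (-2.77).

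Cartilage genes remained high at 38 dpa. EPYC rose by 6.81 (SE 0.29, adjusted p = 2.8e-11, edgeR quasi-likelihood test, Benjamini-Hochberg) to 366 and 490 CPM, and OTOS (6.46), LECT1 (4.93), MATN1 (4.76) and COL9A2 (4.65) rose beside S100A13 (5.65) and C17ORF67 (4.73). PRDX2 was down to 56.5 and 54.4 CPM but still above uninjured (5.90, SE 0.31, or 2.10 against uninjured cells that were not enriched). Chondrocyte genes rose in 9 of 11, 10 when adjusted over the list alone (camera adjusted p = 5.1e-14, adjusted p = 0.063 with an estimated correlation). All 11 S phase genes rose, with MCM7 and MCM6 at 2.19 and CDC6 at 2.13 (camera adjusted p = 4.3e-11, adjusted p = 0.11 with an estimated correlation), and 12 of 14 G2 and M phase genes, among them PLK1 (3.39), CDK1 (2.91), KIF11 (2.27) and AURKA (2.05) (camera adjusted p = 8.3e-08, adjusted p = 0.30 with an estimated correlation). Of 7 glycolysis and hypoxia genes 5 rose (ALDOA 0.85, ENO1 0.80, TPI1 0.71), and the glucose transporter SLC2A1 stood at 27.2 and 47.6 CPM (camera adjusted p = 0.0042, adjusted p = 0.21 with an estimated correlation). Tenocyte genes fell in 2 of 4, TNMD by 2.36 and THBS4 by 0.91 (camera adjusted p = 0.0030, adjusted p = 0.15 with an estimated correlation). HOXA13 was at least 11.2-fold higher and GREM1 at least 4.58-fold lower, while LHX2 (1.75) and KAZALD1 rose. TIMP1 rose by 1.59 and MMP1 fell by 2.07, and the matrix degradation list's median of 0.09 differed in sign from its mean of -0.12 (camera, up, adjusted p = 0.61). JUN (1.12), INHBA (1.17) and ID3 (1.08) rose and TGFB1 fell by 1.31. In all 3314 genes changed, 1769 up and 1545 down, and 1994 without 1 of the uninjured libraries.

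Between 18 and 38 dpa matrix genes came back and many mitotic and patterning genes went down. From 18 to 25 dpa ITLN2 (3.99), FAM198B (2.97), COCH (2.70), TNXB (2.69), SULF2 (2.27), C17ORF67 (2.13) and C2ORF40 (2.06) rose most, and C4ORF43 (-1.50), APOC1 (-1.46), LAMA1 (-1.38), PCP4 (-1.36), IER2 (-1.30) and KAZALD2 (-1.26) fell. FBN1 (1.82), DPT (1.02) and ASPN (1.41) rose, and so did the cartilage genes EPYC, MATN1 (1.34) and HAPLN1 (1.04). HOXA13 rose by 1.23, while SHH went from 2.13 CPM in both libraries to 0 and 0.0297, DKK1 fell by 1.56 and the division gene CENPF by 0.84. COL1A2 stood at -0.18 (adjusted p = 0.39, edgeR quasi-likelihood test, Benjamini-Hochberg), and at 0.04 without cells scored as cycling. The chondrocyte list (4 of 11 up, 5 when adjusted over the list alone), the mature extracellular matrix list (6 of 14 up, 1 down), the fibroblastic CT list (5 of 10 up, 2 down), the ribosome biogenesis list (4 of 9 down, NCL by 1.07) and the immediate early and dissociation stress list (3 of 7 down, JUN by 1.08) passed camera with adjusted p = 0.0014, 0.0080, 0.020, 0.016 and 0.018. With an estimated correlation in camera these became adjusted p = 0.30, 0.44, 0.24, 0.24 and 0.24. Limb progenitor and patterning genes had a median of 0.10 but a mean of -0.90, with 2 rises and 5 falls among 11. In all 2014 genes changed, 999 up and 1015 down, but 915 without 1 of the 25 dpa libraries and 743 after thinning.

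From 18 to 38 dpa the elastic fibre genes FBN1 (5.43, SE 0.16, adjusted p = 1.2e-13, edgeR quasi-likelihood test, Benjamini-Hochberg) and MFAP5 (4.54) rose with ITLN2 (6.98), TNXB (6.09), FAM198B (4.84), SULF2 (4.33), ITIH5 (4.17) and the basement membrane gene COL4A1 (3.98). PRELP (2.92), DPT (2.68), ASPN (2.33), DCN (2.24) and COL1A2 (1.42, SE 0.14) rose too. Mature extracellular matrix genes rose in 13 of 14 and fell in 1, and fibroblastic CT genes rose in 8 of 10 and fell in 2, each the same when adjusted over the list alone (medians 1.87 and 1.69, camera adjusted p = 1.6e-17 and 8.8e-12). S100A10B (-5.00), AW551984 (-4.75), PRDX2 (-4.05), NRGNA (-3.61), OPTC (-3.06), PCP4 (-2.70), APOC1 (-2.36), SPACA4 (-2.26) and FBLN1 (-2.18) fell. Patterning genes fell in 8 of 11 and rose in 1 (MSX1 -2.22, MSX2 -1.85, camera adjusted p = 0.063), and SHH was at least 13.3-fold and GREM1 at least 4.81-fold lower. DKK1, a Wnt antagonist, fell by 4.35 while DKK3 rose by 2.23. Of 14 G2 and M phase genes 10 fell, UBE2C by 1.71 and AURKB by 1.49 (camera adjusted p = 0.0011, adjusted p = 0.55 with an estimated correlation). PCNA fell by 1.23, but stood at 0.03 without cells scored as cycling. Cartilage genes diverged, with EPYC up by 1.64 and COL2A1 (-0.93), MATN4 (-1.33) and COL9A1 (-1.78) down. The proteinase PLAU (2.80), the proteinase inhibitor TIMP1 (2.05) and MMP2 (0.87) rose (3 of 6 matrix degradation genes, 1 fell, camera adjusted p = 0.020, adjusted p = 0.20 with an estimated correlation), as did CNN2 (3.13), ACTA2 (1.77), ALDOA (1.42) and DUSP1 (1.77). Ribosome biogenesis genes fell in 7 of 9, HSPD1 by 1.06 (camera adjusted p = 0.0046, adjusted p = 0.18 with an estimated correlation). The tenocyte list (median 0.12, mean 0.27, test down) and the Wnt Bmp and Tgf-beta signalling list (median -0.16, mean -0.07, test up) differed in sign from their tests (camera adjusted p = 0.71 and 0.65). In all 4522 genes changed, 2183 up and 2339 down, and 2693 after thinning.

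From 25 to 38 dpa the same matrix genes rose, MFAP5 by 3.87, FBN1 by 3.61, ITIH5 by 3.53, TNXB by 3.40, COL4A1 by 2.71, COL4A2 by 2.60, COL5A1 by 1.66, DPT by 1.66 and COL1A2 by 1.60 (SE 0.14, adjusted p = 2.2e-07, edgeR quasi-likelihood test, Benjamini-Hochberg). Mature extracellular matrix genes rose in 13 of 14 (median 1.52, camera adjusted p = 4.4e-20) and fibroblastic CT genes in 8 of 10 (median 1.43, camera adjusted p = 4.1e-14). All 5 contractile and cytoskeletal genes rose (CNN2 2.16, TPM2 1.30), 3 of 6 matrix degradation genes (4 when adjusted over the list alone, PLAU 2.30) and 3 of 7 immediate early genes (4 when adjusted over the list alone, DUSP1 1.80, JUNB 1.07), each with camera adjusted p = 0.0099 and adjusted p = 0.21, 0.16 and 0.16 with an estimated correlation. Chondrocyte genes fell in 7 of 11 (COL9A1 -2.03, MATN4 -1.83, HAPLN1 -1.75, COL2A1 -1.28, camera adjusted p = 0.0018, adjusted p = 0.17 with an estimated correlation), patterning genes in 4 of 11 (MSX1 -2.66, HOXA13 -2.10, MSX2 -2.09, camera adjusted p = 0.029, adjusted p = 0.28 with an estimated correlation), S phase genes in 5 of 11 (PCNA -1.46, camera adjusted p = 0.0099, adjusted p = 0.16 with an estimated correlation) and G2 and M phase genes in 8 of 14 (UBE2C -1.90, camera adjusted p = 0.0018, adjusted p = 0.34 with an estimated correlation). The authors' cluster led by OTOS, LECT1 and COL2A1 held 969 of 2977 and 2001 of 6042 cells at 25 dpa but 12 of 576 and 80 of 2285 at 38 dpa, so a fall of cartilage genes within cells was not told apart from a change in which cells were present. S100A10B (-4.38), AW551984 (-4.24), PRDX2 (-3.25), NRGNA (-2.93), DKK1 (-2.79), OTOS (-2.18), OPTC (-2.10) and RASL11B (-1.96) fell. HBB (-3.94) and HBA (-3.15), genes of red blood cells, fell from a 25 dpa level at which HBB stood at 68.1 and 246 CPM. In all 3568 genes changed, 1734 up and 1834 down, but 2171 without 1 of the 38 dpa libraries and 1991 after thinning.

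Across these comparisons the calls for fibroblastic CT genes held with an estimated correlation in every case except 25 against 18 dpa, with adjusted p from 0.010 to 0.034. Those for mature extracellular matrix held at 18 and 25 dpa against uninjured, from 18 and from 25 to 38 dpa, and in the enrichment comparison, and the chondrocyte call held only at 25 dpa against uninjured (adjusted p = 0.037, camera). With fry 13, 14 and 10 of 16 lists passed at 18, 25 and 38 dpa against uninjured, where camera called 6, 8 and 7. From 18 to 25, 18 to 38 and 25 to 38 dpa fry called 7, 10 and 12 and camera 5, 5 and 9. For enrichment fry called 10 of 13 lists and camera 7. PRRX1 stood at no more than 1.17 CPM in any CT-enriched library, with 5 to 25 counts per group. Against CT-enriched uninjured cells no change was called (-0.81 at 18 dpa, adjusted p = 0.43, -1.45 at 25 dpa, adjusted p = 0.18, and -0.60 at 38 dpa, adjusted p = 0.63, or 0.35 without 1 of the 38 dpa libraries, edgeR quasi-likelihood test, Benjamini-Hochberg). Against uninjured cells that were not enriched PRRX1 fell on each day, by -2.23, -2.88 and -2.08 (adjusted p = 0.0027, 0.00054 and 0.013, edgeR quasi-likelihood test, Benjamini-Hochberg). Plate-based cells went the other way at 18 dpa (2.44 against 1.20 in uninjured arm), so the direction for PRRX1 stayed open.

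In the uninjured arm the CT-enriched libraries held more of fibrous matrix genes and far less of blood genes than those not enriched. The connective tissue cells that the authors kept differed between these libraries as well. COL1A2 at 18 dpa stood at -2.48 against the enriched and -0.30 against the not enriched cells, and OGN at -3.43 and -0.70. The differences below are therefore not due only to the removal of other cell types. OGN rose by 3.70 (SE 0.06, adjusted p = 7.6e-13, edgeR quasi-likelihood test, Benjamini-Hochberg), from 338 and 330 to 4434 and 4234 CPM, and MFAP5 (3.63), FAM198B (3.61), COL3A1 (3.51), SERPINF1 (3.14), SPARC (3.14), COL1A1 (3.12), COL1A2 (3.10, SE 0.05), CLU (3.10) and LUM (2.67) rose. HBB fell by 11.79 (SE 0.08), from 22395 and 22545 CPM to 6.71 and 6.06, with HBA-L5 (-11.76), HBG1 (-10.97), S100P (-9.27), S100A10B (-8.90) and PRDX2 (-8.89), and the immunoglobulin gene IGJ was at least 1057-fold lower. All 7 measured fibroblastic CT genes and 10 of 11 mature extracellular matrix genes rose, also when adjusted over the list alone (fibroblastic CT median 2.67, camera adjusted p = 4.2e-49 and 1.0e-50). Chondrocyte genes rose in 5 of 7 (COL9A2 6.18, COL2A1 2.48, camera adjusted p = 2.1e-06, adjusted p = 0.20 with an estimated correlation), matrix degradation genes in 3 of 5 (MMP14 2.43, camera adjusted p = 0.047, adjusted p = 0.48 with an estimated correlation) and G2 and M phase genes in 7 of 11 (BUB1 2.49, TOP2A 1.56, camera adjusted p = 0.047, adjusted p = 0.38 with an estimated correlation). Immediate early genes rose in 5 of 6 (IER2 1.81, FOSB 1.34, camera adjusted p = 0.047, adjusted p = 0.42 with an estimated correlation) and Wnt Bmp and Tgf-beta genes in 3 of 8 (TGFB2 1.71, TGFB1 1.54, camera adjusted p = 0.047, adjusted p = 0.38 with an estimated correlation). VCAN rose by 2.59 and IL1B fell by 3.75, and the wound inflammation list had a median of -0.32 against a test pointing up (camera adjusted p = 0.85). In all 7222 of 15834 contigs changed, and 3869 with DESeq2. These sums take in every deposited barcode, including 493 of 843 and 582 of 1256 in the CT-enriched libraries that the authors did not keep.

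In the libraries that were not enriched, 63.4% (60.6 to 66.1, exact Clopper-Pearson) and 61.6% (58.8 to 64.4) of 1198 and 1181 cells fell in clusters of the authors that are like connective tissue by their markers. Clusters like red blood cells (HBB, HBA, ALAS2) held 11.4% and 12.2%, like macrophages (LYZ, C1QB, C1QC) 9.77% and 9.40%, like lymphocytes (TRAC, CD3E) 7.76% and 8.21%, like muscle (ACTA1, CKM) 2.34% and 2.37%, like endothelium (VWF, LYVE1) 1.75% and 2.20%, and like epidermis (KRT5, EPCAM) 1.09% and 1.44%, while 2.59% and 2.54% stayed unnamed. With Leiden clusters in place of the authors' clusters, none was like lymphocytes (0% in both libraries), and at resolution 0.5 epidermis held 2.42% and 3.56% and unnamed cells 8.51% and 9.65%. With each cell assigned by its highest marker score, connective tissue held 46.6% and 46.4%, epidermis 7.35% and 6.44%, muscle 5.43% and 5.00% and unnamed 0%. The lineage reporter mCherry had a UMI in 80.8% and 79.3% of connective tissue-like cells (1206 and 1105 CPM, median depths of 8027 and 7645.5 UMIs) beside a background of 35.3% and 29.2% of red blood cell-like cells (28.3 and 20.3 CPM, 18862 and 16415 UMIs).

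Other cell types' markers moved with the day in the CT-enriched libraries. Per plain library total, erythroid markers summed to 8.10 and 10.6 CPM in uninjured, 27.2 and 8.86 at 18 dpa, 72.8 and 252 at 25 dpa and 5.97 and 14.9 at 38 dpa. Macrophage markers were 82.1 and 83.5, then 34.0 and 41.9, 28.3 and 31.3, and 48.9 and 76.3 CPM. Endothelium markers, carried at 18 dpa by VWF (17.3 and 16.7), were 5.06 and 2.93, then 18.1 and 17.6, 11.7 and 10.7, and 5.55 and 9.63. Melanocyte markers, carried at 18 dpa by PMEL alone (13.0 and 7.94), were 2.03 and 2.13, then 13.6 and 8.32, 11.4 and 10.7, and 1.49 and 2.57. Skeletal muscle markers were 17.7 and 12.5, then 2.82 and 1.73, 11.1 and 40.8, and 25.6 and 44.2. Pericyte or smooth muscle markers went from 19.8 and 20.5 to 45.4 and 38.5 CPM at 38 dpa, and epidermis markers, carried by KRT8, KRT18 and CDH1, from 4238 and 4092 to 7948 and 6904. Lymphocyte, Schwann and thrombocyte markers stayed at or under 0.786, 0.640 and 3.64 CPM in every library and neutrophil markers at 0. Connective tissue markers fell from 125342 and 126170 to 18278 and 21282 CPM at 18 dpa and stood at 64822 and 68135 at 38 dpa.

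In plate-based cells, proteinase, provisional matrix and division genes were high at 3 dpa and fibrous matrix genes low. At 3 dpa the collagenase MMP1 averaged 7.41 against 0.16 (SD 0.18 between the uninjured sets) on the log2(value + 1) scale and was found in 97.2% of cells against 5.56%. TIMP1 was 6.92 higher, the antibacterial enzyme LYZ 6.81 (in a set whose mean macrophage marker level was 1.53 against 0.204), the provisional matrix gene TNC 6.28 (8.02 against 1.74, SD 0.62) and SDC1 5.97. IL11, a cytokine of injured tissue, averaged 4.38 and was found in 70.4% of cells against 0% in uninjured arm, and PCNA (5.22), TGFB1 (3.68), FBL (3.57), HSPD1 (3.54), HAS2 (3.05) and PRRX1 (2.22) were higher too. OGN averaged 4.75 against 9.26 (SD 0.60), and TAT (-4.29), TNXB (-4.08), APOH (-3.63), EMP2 (-3.33), FBN1 (-2.19), DPT (-2.07) and MFAP5 (-2.06) were lower. The matrix degradation median was 1.47 higher (percentile 99.96 of matched random lists), provisional extracellular matrix 2.14 (99.6) and S phase 1.97 (100), and that of mature extracellular matrix was lower (-1.38, percentile 0).

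At 5 and 8 dpa the elastic fibre genes and DPT were further below uninjured arm than at 3 dpa, and division genes were high, with S phase medians of 1.45 and 2.26 after 1.97 at 3 dpa. KAZALD2, a secreted blastema protein, was 7.63 higher at 5 dpa and 7.45 at 8 dpa, TGFBI 6.83 and TNC 6.53 at 5 dpa, and KPNA2 6.83, AW551984 6.79, NMRK2 6.70 and ANP32E 6.62 at 8 dpa. PCNA was 4.85 and then 6.54 higher, and UBE2C 6.41 and CDK1 5.37 at 8 dpa. MMP1 (4.63, 5.06) and IL11 (3.44, 3.36) remained high. The patterning genes SALL4 (2.33 and 2.21) and HOXD11 (2.78 at 8 dpa) were higher. DPT (-3.02, -4.90), FBN1 (-3.44, -4.55) and MFAP5 (-2.70, -4.36) were lower, with TNXB (-4.89, -5.05), ADH4 (-4.28, -4.67) and, at 8 dpa, PLAC9 (-5.05). FBLN1, also of the fibroblastic CT list, was 3.79 higher at 8 dpa and 4.97 at 11 dpa, and 3 of the 10 members had higher means on both days. PRRX1 was 3.16 higher at 5 dpa and 3.51 at 8 dpa.

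At 18 dpa cartilage genes were among the highest, after a smaller difference of their median at 11 dpa. NREP was 8.49 higher at 11 dpa (8.83, SD 0.71, against 0.34, SD 0.38) and 7.64 at 18 dpa. COL11A1 was already 2.22, 4.42 and 3.98 higher at 3, 5 and 8 dpa and 4.20 at 11 dpa. MATN4 (5.00), COL2A1 (3.13) and COL9A1 (2.32) were higher at 11 dpa, and at 18 dpa COL2A1 averaged 7.45 against 0.72 (SD 0.29), with COL11A1 5.62, COL9A1 5.30 and MATN4 4.92 higher. HOXD11 (4.04), LHX9 (2.40), HOXA9 (2.10) and PRRX1 (3.81) were higher at 11 dpa, as were UBE2C (6.07), PCNA (6.05), AURKB (5.70), RRM1 (5.56), DKC1 (4.37) and CNN2 (4.14). MFAP5 averaged 0.96 at 18 dpa against 8.79 (SD 0.69), and DPT (-5.98 at 11 dpa, -7.54 at 18 dpa), DCN (-3.09, -4.77) and COL1A2 (-2.35 at 18 dpa) were lower. Division genes were smaller in difference at 18 dpa (PCNA 3.18, UBE2C 2.30).

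**Figure D2:**
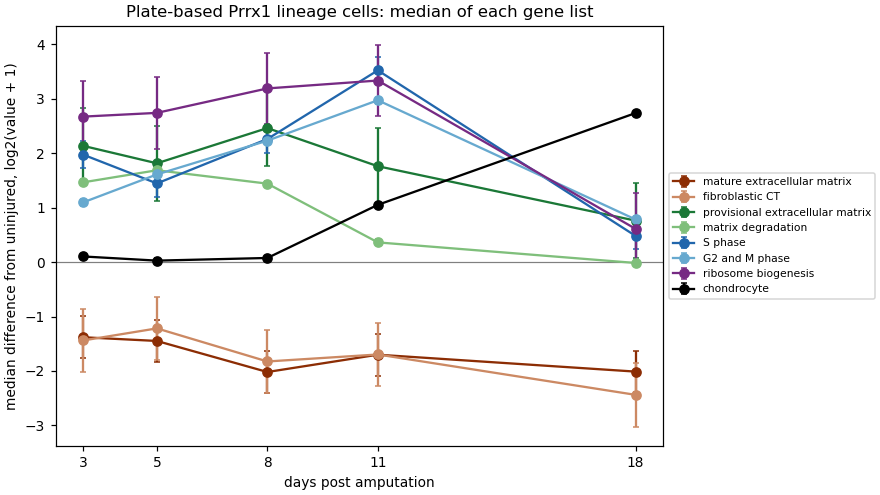
Median difference from uninjured, in log2(value + 1), of 8 gene lists in plate-based Prrx1 cells against day after amputation (3, 5, 8, 11, 18). Bars give the SD of the list median between uninjured sets, and the chondrocyte median reached 2.74 at 18 dpa.

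The list medians over 3, 5, 8, 11 and 18 dpa traced this order. Mature extracellular matrix stood at -1.38, -1.45, -2.02, -1.70 and -2.01 (SD between uninjured sets 0.38), or at -2.10, -2.54, -2.92 and -3.25 at 3, 5, 8 and 11 dpa with quantile normalization, and fibroblastic CT at -1.44, -1.22, -1.83, -1.70 and -2.44 (0.58). Matrix degradation went from 1.47, 1.69 and 1.44 to 0.36 and -0.02 (SD 0.05), G2 and M phase through 1.10, 1.61, 2.23, 2.98 and 0.78 (0.07), S phase through 1.97, 1.45, 2.26, 3.52 and 0.48 (0.25), and chondrocyte from 0.10, 0.03 and 0.08 to 1.05 and 2.74 (0.04). Limb progenitor and patterning stood at 0.67 at 8 dpa and 1.03 at 11 dpa (percentile 99.99 at both) and 0.00 at 18 dpa, whereas 7 of 11 measured members rose in the 10x libraries at 18 dpa. Ribosome biogenesis stood at 3.34 at 11 dpa and 0.61 at 18 dpa. Tenocyte was highest at 11 dpa (0.62, SD 0.27, percentile 68.9, with THBS4 at 3.71 and TNMD at 2.14), periskeletal at 11 dpa (0.07, SD 0.09), osteoblast or hypertrophic at 8 dpa (0.09, SD 0.06) and wound inflammation at 3 dpa (0.22, SD 0.03, percentile 80.8). Contractile and cytoskeletal, glycolysis and hypoxia, immediate early and dissociation stress, and Wnt Bmp and Tgf-beta signalling stood at 1.70, 1.48, 0.44 and 0.56 at 11 dpa (percentiles 50.2, 61.0, 3.62 and 6.79) and at -0.30, -0.24, -0.51 and -0.09 at 18 dpa, and immediate early at -0.35 and -0.20 at 3 and 5 dpa (percentiles 0.02 and 0.09). With quantile normalization all 4 turned below 0 at 11 dpa, as did matrix degradation (-0.0658). At 3, 8 and 18 dpa a single set was measured, so no replicate check exists for those days, and the median of genes detected per cell ran from 1767 to 2430 in uninjured sets, 2898 at 3 dpa, 3528 to 4719 at 11 dpa and 1868 at 18 dpa.

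The sets of the latest limbs differed from each other. The set labelled 3mpa appears as 1apa in the deposited table, so a difference between time points was not told apart from one between sets. At 3mpa, COL3A1 (2.78), POSTN (2.32), THBS4 (2.63) and FBN1 (2.06) were higher than in uninjured arm, the mature extracellular matrix median was 0.71 higher (percentile 100), and BHMT (-3.76), FCNB (-3.26), TAT (-3.20), AHCY (-3.02), RBP4 (-2.78) and EGR1 (-2.45) were lower. LYZ (4.12) and C1QC (3.32), genes of macrophages, were higher in the same set, where the mean macrophage marker level was 2.16 against 0.204 in uninjured arm. TGFBI (4.10), SLC2A8 (3.55) and EIF4E (3.24) were higher too. At 1apa 887 genes were detected per cell, and nearly all genes beyond the size rule were lower, among them SPACA4 (-5.51), EMP2 (-4.53), LDHB (-4.49), HSPA8 (-4.45), RAN (-4.31) and PDGFRA (-3.18), with only MGC75752 (2.22) and IGFBP3 (2.13) among the named genes higher. Each of these groups is a single set.

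Blastema profiles came closest to limb buds at 11 dpa. The mean correlation with stages 40 and 44 was 0.505 in uninjured arm (SD of set pairs 0.0592), 0.640, 0.722, 0.741 and 0.843 at 3, 5, 8 and 11 dpa, 0.755 at 18 dpa, 0.427 at 3mpa and 0.267 at 1apa, where it was -0.147 over the 300 most variable genes (0.146 in uninjured arm and 0.772 at 11 dpa). Apart from 18 dpa (1868), the number of genes detected per cell broadly followed this order, with set medians of 887 at 1apa, 1767 to 2430 in uninjured arm, 2085 at 3mpa, 2898 at 3 dpa and 3528 to 4719 at 11 dpa, against 3716 at stage 40, so a part of this order due to detection was not excluded. Stage 28, measured by another method than the Prrx1 cells, reached at most 0.508 among the Prrx1 groups (11 dpa). It reached 0.526 with Col1a2 cells at 11 dpa, which were measured by the same method as stage 28 (SmartSeq2). The 3mpa and 1apa profiles correlated at 0.937 and 0.892 with uninjured arm, beside 0.896 to 0.948 between the uninjured sets. Blastema cells of the Col1a2 line at 11 dpa correlated at 0.866 with Prrx1 cells of the same day, 0.837, 0.803 and 0.790 with those at 5, 8 and 18 dpa and 0.632 with uninjured Prrx1 cells, across 2 methods and 2 tables that were processed apart. The Col1a2 sets had medians of 4645 to 7048 genes detected per cell. Median correlation between cells of a set was 0.443 in uninjured arm (SD 0.0424) and 0.528 at 11 dpa, but 0.493 and 0.416 among cells matched on detected genes, which rest on 13 and 26 cells of 2 of the 4 uninjured sets and on 17 cells of 1 of the 2 sets at 11 dpa.

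**Figure D3:**
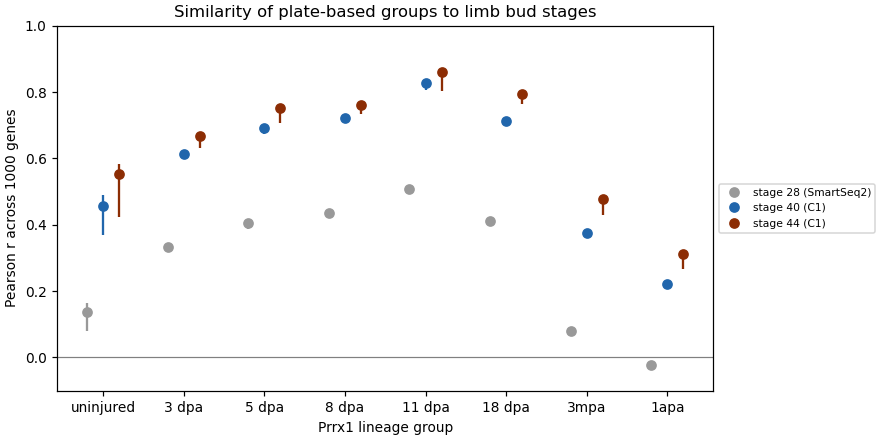
Pearson correlation over 1000 variable genes between 8 groups of plate-based Prrx1 cells and limb field or bud stages 28 (grey), 40 (blue) and 44 (red), with lines for the range over pairs of sets. The mean with stages 40 and 44 was 0.843 at 11 dpa and 0.505 in uninjured arm.

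By the authors' classes, 31.5% of 108 uninjured plate-based cells were fCTI, 26.9% fCTIII, 19.4% fCTIV, 13.0% fCTV, 5.56% periskeletal and 3.70% tendon. At 3mpa (named 1apa in the deposited table) 57.1% of 77 cells were fCTI, 26.0% fCTIII and 10.4% tendon, and at 1apa 33.3% and 60.8% of 51 cells were fCTI and fCTIII. No fCTIV cell was found at 3mpa or 1apa, where the exact upper limits are 4.68% and 6.98%, but uninjured sets differed in this class too (8 of 24, 11 of 35, 1 of 34 and 1 of 15 cells).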

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

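Of the 7 tests of technical explanations below, 6 were chosen only after the result they concern had been seen. Only the test of a few cells that hold most of the IBSP counts was written before its result. The 3 patterns were picked after several candidates had been looked at.

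PRDX2 was weighed because it rose most at 18 dpa among genes with mean log2 CPM of at least 5, while it marks red blood cells in the uninjured arm. RNA from red blood cells was excluded, because the 18 dpa libraries held 0.0288 HBB counts per PRDX2 count at most (0.0112 in the other library), against 96.2 to 99.5 in the red blood cell-like cells. Reads of the related PRDX1 were excluded, since in plate-based cells PRDX2 differed by -4.30 between 3 and 18 dpa while PRDX1 differed by 1.21 in the other direction. Depth was excluded, because with every library thinned to the same total PRDX2 still had a log2 fold change of 10.45 (adjusted p = 1.4e-19, edgeR quasi-likelihood test, Benjamini-Hochberg). A rise of PRDX2 inside blastema connective tissue cells is therefore kept as a hypothesis, with plate-based sets at 4.11 to 4.80 at 11 dpa and 4.44 at 18 dpa against 0 to 0.608 in uninjured arm.

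IBSP was weighed because its fall at 18 dpa rested on 1 of the 2 uninjured libraries. Depth was excluded, because the richer library kept 408 counts (369 to 450, exact Poisson interval) after thinning to the total of the other, which had 1 (upper bound 5.57). A few cells fit instead, as the 1% of cells with most IBSP held 100% of its counts. In that library 7 of 674 cells (1.04%) had any IBSP and a single cell held 750 counts, and in the other 1 of 350 cells had any. The fall is thus a matter of which rare cells were caught.

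LYZ was weighed because it stood among the highest genes of the single 3 dpa set and is a macrophage gene. The number of genes detected was excluded, because the 5 and 8 dpa sets, with more genes per cell, reached only 3.05 (lowest 2.21) against 7.19. RNA from macrophages remained open. LYZ followed 8 other macrophage markers across the 108 cells only weakly (Spearman rho 0.239), and C1QC per LYZ was 0.0510, against 0.320 in macrophage-like cells and 0.243 at 3mpa. Whether connective tissue cells or macrophages carry the LYZ could not be decided from these values.

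Barcodes that the authors left out of their tables held far more red blood cell RNA at 25 and 38 dpa than in the CT-enriched uninjured libraries. Per plain total, erythroid markers stood at 27629 and 40078 CPM in the 128 and 157 such barcodes at 25 dpa and at 2472 and 9399 CPM in the 153 and 385 at 38 dpa, against 10.1 and 8.63 in CT-enriched uninjured and 763 and 3066 in the libraries that were not enriched, while the 18 dpa libraries differed from each other (1905 and 0.998 CPM). Endothelium markers stood at 189 and 62.3 CPM at 25 dpa against 3.74 and 2.42. Connective tissue markers at 38 dpa stood at 174745 and 143840 CPM in the left-out barcodes, against 38801 and 40624 in kept cells. In CT-enriched uninjured libraries these were 80578 and 95170 against 70155 and 70385. In the libraries that were not enriched the left-out barcodes held less (3703 and 3691 against 9168 and 8985). The tests at 38 dpa therefore describe only kept cells. Barcodes outside the tables entered only the alternative that takes all cells of a library and, for the uninjured arm, the comparison of enriched with not enriched libraries. Why they were left out is not stated in the labels.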

How the results depend on the processing

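Of 491 named 10x calls, 262 passed under every alternative and 455 never changed sign, and of 7987 alternative results 7463 stayed the same, 475 became weaker, 4 stronger and 45 reversed. Of 1292 plate-based list results 951 stayed the same, 324 moved and 17 reversed, and of 5987 plate-based gene results 4786 stayed the same, 1197 moved and 4 reversed. The rule by which a plate-based gene counts as reversed was changed, after the labels had been seen, to the planned size rule. Below that rule, 35 named genes and 10 list medians changed sign under quantile normalization, 8 and 7 under the share of cells above 1, and at most 7 and 6 under any other setting. The reference made of uninjured cells that were not enriched and the values rescaled to an equal total were chosen after the data had been seen. No paired analysis was possible because the labels name no animal or preparation that links libraries of different groups. When a library is left out, the lone library of its group is assumed to vary like the other groups. Plate-based cells restricted to connective tissue and a size threshold of 1 give no separate values, and the planned number of genes past the size rule is not given. The cause of a difference was not tested unless stated.

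Without each library in turn, the genes that changed numbered 3543 to 4942 at 18 dpa, 3139 to 4797 at 25 dpa and 1994 to 3680 at 38 dpa against uninjured, 915 to 2260 from 18 to 25 dpa (915 and 1071 without either 25 dpa library), 3355 to 4547 from 18 to 38 dpa, 2171 to 4010 from 25 to 38 dpa, and 5513 to 6667 for enrichment. The lowest values came without the second uninjured library at 38 dpa and without the second 38 dpa library from 25 to 38 dpa. Lists past camera numbered 6 to 6, 7 to 10, 7 to 7, 5 to 6, 5 to 6, 8 to 9 and 3 to 8 in the same order, with the 3 reached without the first library that was not enriched. Against uninjured, IBSP ranged from -6.54 to 4.68 at 18 dpa, -6.97 to 2.30 at 25 dpa and -5.74 to 4.42 at 38 dpa, with the highest values without the second uninjured library, which follows from the few cells that hold its counts. PRRX1 ranged from -1.27 to 0.35 at 38 dpa (highest without the second 38 dpa library), and from -0.50 (without the first 38 dpa library) to 1.13 between 18 and 38 dpa, with -0.14 without the first 18 dpa library. COL1A2 ranged from -0.37 to 0.0421 between 18 and 25 dpa, the latter without the second 18 dpa library.

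With a null of a log2 fold change of 1, 1874, 1487 and 702 genes passed against uninjured at 18, 25 and 38 dpa, 110 from 18 to 25, 802 from 18 to 38 and 304 from 25 to 38 dpa. DESeq2 gave 1326 from 18 to 25 dpa and 3869 for enrichment. Thinning gave 743, 2693 and 1991 from 18 to 25, 18 to 38 and 25 to 38 dpa. With no filter beyond 1 count, 3 lists passed from 18 to 25 dpa. With all cells of the libraries IBSP stood at 0.44 at 38 dpa.

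Without cells scored as cycling, 1189 genes changed from 18 to 25 dpa. Then 3, 4, 3 and 5 lists passed at 18 and 25 dpa against uninjured and from 18 and from 25 to 38 dpa, after 6, 8, 5 and 9 with all cells. Removing cells chosen by S phase and G2 and M phase genes takes these lists away by construction. That does not cover the whole drop, so calls of other lists were lost in each comparison as well. CDC6 (-0.34), TIMP1 (0.58) and ALDOA (0.0110) reversed at 18 dpa against uninjured, TNMD (0.0425), ALDOA (-0.0343) and COL1A2 (0.0445) from 18 to 25 dpa, PCNA (0.0306) from 18 to 38 dpa and MKX (-0.49) from 25 to 38 dpa.

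With uninjured cells from the libraries that were not enriched, KERA (0.16), IBSP (10.83), PLAU (0.14), MMP14 (0.76), MMP2 (0.79), VCAN (0.56) and JUNB (0.70) reversed at 18 dpa. At 25 dpa IBSP (8.45), NFKBIA (0.19), PLAU (0.63), MMP14 (0.74), VCAN (0.12), NOP58 (-0.40) and IER2 (1.40) did. At 38 dpa 4 lists passed, and MFAP5 (0.41), FBN1 (0.35), OGN (1.10), IBSP (10.53), NFKBIA (0.18), MMP14 (0.93), COL1A1 (0.70), VCAN (0.16), SDC1 (-0.36), THBS1 (-0.26), CNN2 (0.17), FBL (-0.21), HSPD1 (-0.25), JUNB (0.77) and COL1A2 (1.07) reversed.

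For plate-based lists, quantile normalization gave mature extracellular matrix medians of -2.10, -2.54, -2.92 and -3.25 at 3, 5, 8 and 11 dpa and -0.15 at 1apa. Rescaled values gave -1.88, -2.67, -2.36 and -2.51 at 5, 8, 11 and 18 dpa, and a pseudocount of 0.1 gave -1.78 at 1apa. Without each set in turn this median ranged from -1.55 to -1.21, -1.59 to -1.28, -2.16 to -1.85, -1.90 to -1.59 and -2.26 to -1.82 at 3, 5, 8, 11 and 18 dpa, 0.56 to 0.76 at 3mpa and -1.47 to -1.19 at 1apa. Under quantile normalization the limb progenitor (-0.00940) and Wnt Bmp and Tgf-beta (-0.0126) medians reversed at 3 dpa, wound inflammation (-0.0136) and glycolysis (-0.19) at 8 dpa, and at 11 dpa osteoblast (-0.14), wound inflammation (-0.0545), matrix degradation (-0.0658), provisional extracellular matrix (-0.32), contractile (-0.00932), glycolysis (-0.13), immediate early (-0.60) and Wnt Bmp and Tgf-beta (-0.14), as did ENO1 (-0.00704), MMP2 (-0.17) and TBX5 (-0.15). At 1apa the chondrocyte (0.000430), contractile (0.72) and immediate early (0.20) medians and TPM1 (0.0628) reversed. With the filter on mean value, limb progenitor at 3 dpa (-0.0401) and wound inflammation at 11 dpa (-0.0660) reversed.

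Similarity to stages 40 and 44 over 300 genes was 0.146, 0.384, 0.533, 0.602, 0.772, 0.634, 0.0349 and -0.147 in uninjured, 3, 5, 8, 11 and 18 dpa, 3mpa and 1apa, and over all genes detected in at least 5% of cells 0.781, 0.874, 0.902, 0.908, 0.940, 0.881, 0.731 and 0.624. Spearman correlation gave 0.605 in uninjured, 0.711 at 8 dpa, 0.561 at 3mpa and 0.496 at 1apa. Without each set in turn the ranges were 0.494 to 0.524, 0.628 to 0.646, 0.702 to 0.729, 0.731 to 0.745, 0.817 to 0.851, 0.747 to 0.757, 0.419 to 0.433 and 0.260 to 0.275. Similarity between cells was 0.493 in uninjured, 0.433 at 8 dpa and 0.416 at 11 dpa when matched on detected genes, and 0.490 in uninjured, 0.475 at 3mpa and 0.437 at 1apa over 300 genes.

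Among cell classes of the libraries that were not enriched, assignment by the highest marker score gave 46.6% and 46.4% connective tissue, 7.35% and 6.44% epidermis, 5.43% and 5.00% skeletal muscle and 0% unnamed. Leiden resolution 0.5 gave 2.42% and 3.56% epidermis, 0% lymphocyte and 8.51% and 9.65% unnamed, and resolution 2 gave 2.09% and 2.79% epidermis, 0% lymphocyte, 9.68% and 10.8% unnamed and 58.7% connective tissue in the second library.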

Other observations

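Limb bud cells carried the Cre driver genes in another balance than arm cells. On the log2(value + 1) scale COL1A2 averaged 0, 1.24 and 1.27 at stages 28, 40 and 44, against 10.70 in uninjured Prrx1 cells and 9.03 at 11 dpa. PRRX1 averaged 2.24, 4.52 and 4.39 at these stages and 1.20 (SD 0.16) in uninjured arm, and went through 3.42, 4.36, 4.71 and 5.02 at 3, 5, 8 and 11 dpa to 2.44 at 18 dpa, 2.01 at 3mpa and 0.66 at 1apa. In the Col1a2 line at 11 dpa, PRRX1 averaged 5.44 and COL1A2 10.05, in a table processed apart from the Prrx1 cells. Stage 28 and the Col1a2 cells were measured with SmartSeq2 and the other groups here with C1. Limb buds were not sorted, and their mean connective tissue marker level was 2.71 at stage 40 and 2.48 at stage 44 against 7.58 in uninjured arm.

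PRDX2 was also found in limb buds, where sets averaged 0.983 to 2.63, and stayed at or under 0.276 at 3, 5 and 8 dpa. Macrophage marker levels in the plate-based sets were 0.708, 0.748 and 0.723 at 5, 8 and 11 dpa and 0.188 at 18 dpa. Erythroid marker levels were at most 0.247 in the arm and blastema sets (3mpa).

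The paired 10x libraries correlated at 0.988 to 0.995 on log2 CPM, yet differed by more than counting error, with a chi-square per degree of freedom of 3.31 in CT-enriched uninjured arm, 5.90 where no enrichment was done, 114 at 18 dpa, 15.8 at 25 dpa and 11.0 at 38 dpa. The 18 dpa libraries also differed in cells and depth, with 2684 cells at a median of 9568.5 UMIs in 1 and 7255 cells at 3571 UMIs in the other. An mCherry UMI was present in 96.5% to 99.96% of the cells the authors kept in each CT-enriched library.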
